A study of Zea mays subsp. mays with 2 samples.

How the data were processed

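Transcript levels were measured by Illumina mRNA sequencing of maize endosperm, the starch- and protein-storing tissue of the kernel, taken 18 days after pollination from wild-type and dek35 mutant kernels. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase I treatment and made into libraries with standard Illumina reagents. The submitters' design text speaks of triplicates, whereas the labels give 1 sample per genotype, each with 1 column of values. Whether those values come from 1 library or from pooled or averaged replicates is not given in the sources used here, so each genotype was treated as 1 library.

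The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), calculated by the authors, per the file headers. The submitters' processing notes name Bowtie 0.12.2. The program that computed FPKM, the genome build, the gene models, the use of strand and any further scaling between the libraries are not given in the sources used here. Each row of the deposited FPKM tables is a locus given by chromosome, start and end, without a gene name. Both tables list the same 43446 loci in the same order, and they were joined row by row because 9298 rows share their coordinates with another row. No value is exactly 0; 3495 loci in dek35 and 6019 in wild type are at 1e-05, and 4 and 5 are below it. Values of 1e-05 or less are described here as listed at 0. Starts in the files count from 0 and are printed here counted from 1.

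Gene names were taken from a table of the Zm-B73-REFERENCE-NAM-5.0 annotation where a locus had exactly the start and end of an annotated gene. On the mitochondrial genome, 7 of 37 loci matched in this way, and 23 had a start or an end equal to that of a gene they overlap. On chromosomes 1 to 10, 0 of 43287 loci matched, so the nuclear coordinates were taken as those of another build and no nuclear locus was named. Of 32 gene lists fixed beforehand (storage proteins, starch synthesis, respiration, stress, cell type markers and others), 31 could therefore not be applied; the list of mitochondrially encoded proteins had fewer than 3 loci over the minimum and was given no median. The locus of the dek35 gene was not analysed here, so the genotype labels could not be checked against its level.

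The comparison was planned for counts and was run on FPKM instead, as fixed for that case before the data were examined. Loci with at least 5 FPKM in at least 1 library were entered, and the ratio was log2((dek35 + 1)/(wild type + 1)), a scale that understates the change of low loci. With 1 library per genotype, no test of the genotypes was possible and no p-value is given. Loci are described as higher or lower at a ratio of at least 2-fold, and also at 4-fold. Because the median log2 ratio of all loci entered was far from 0, ratios are also given relative to that median. The rule for naming loci was fixed beforehand: the 2 highest and 2 lowest ratios among loci with at least 10 FPKM in 1 library, since no nuclear locus had a name, and every mitochondrial nad gene. Groups of neighbouring abundant loci were defined after the data were seen, as at least 3 loci of 200 bp or more with a mean of at least 500 FPKM over both libraries and gaps of at most 1 Mb. The median ratio of each group was placed among 10000 random sets of the same size drawn from all abundant loci, as a description of these libraries.

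The number of reads behind each value is unknown, so no counting interval is given. Where both libraries hold a single fragment, the ratio of their FPKM is the ratio of what 1 fragment is worth. Among 3663 loci that summed to under 0.5 FPKM and were above 0 in both libraries, the most frequent ratio of dek35 to wild type was 0.859 (0.841 to 0.901 over 200 resamplings). The median log2 ratio of the same loci was 0.31, in the other direction, so the relative depth of the libraries was not settled. Transcript lengths are not in the tables, so whole reads were not recovered.

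Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedure was tested on simulated data built from the wild-type values of 15212 loci, with a shift of 0.5 (log2) for all loci and 8-fold changes (log2 of 3) planted in single loci and in 1 chromosome window. It returned a median of 0.48, recovered 100.0% of raised and 100.0% of lowered loci at 2-fold, and called 0.05% of unchanged loci. The simulated noise was set by hand and held no counting noise. Changes were planted only in loci well above the minimum level. These rates therefore follow from the chosen settings and are not error rates for the real libraries. The planted window ranked first, 5.2 percentage points below the highest share in shuffled positions, so a window of this size can be missed. Alternatives covered the scaling between libraries, the minimum level, the pseudocount and, added after the data were seen, the removal of loci under 200 bp, of rows that share coordinates and of loci listed at 0 in either library. For the groups of neighbours, 1 row was also kept for each pair of coordinates, the one with the highest mean FPKM.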

Results

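Endosperm transcripts of wild-type maize and of the defective-kernel mutant dek35 were profiled at 18 days after pollination, with 1 library per genotype. The dek35 locus is known to encode a pentatricopeptide repeat protein that acts on the splicing of the mitochondrial nad4 transcript, nad4 being a subunit of respiratory complex I. The deposited tables gave FPKM for 43446 loci. In the dek35 library 39947 loci lay above 1e-05, 26063 reached 1 FPKM and 16677 reached 5 FPKM. In the wild-type library the corresponding numbers were 37422, 22550 and 13010. Read numbers are unknown, and no difference below has a replicate check or a test.

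The first question was how the 2 endosperm transcriptomes differed in composition. A few loci dominated the wild-type library and did not dominate the dek35 library. The 10 most abundant wild-type loci held 38.3% of all summed FPKM in wild type, and the same 10 loci held 1.77% in dek35. All 10 were at least 4-fold lower in dek35, and their summed FPKM was 470466 in wild type and 18766 in dek35, a 25.1-fold difference (45.0-fold with median-of-ratios size factors). The 50 most abundant wild-type loci held 59.6% of summed FPKM in wild type and 10.7% in dek35. Of these 50, 30 were at least 4-fold lower, 36 at least 2-fold lower and 3 at least 2-fold higher in dek35 as deposited; relative to the median ratio of all loci compared, described further on, these numbers were 34, 40 and 0. Only 2 of the 50 were listed at 0 in dek35. In the dek35 library the 50 most abundant loci held 22.6% of summed FPKM, and 18 of them were also among the 50 most abundant of wild type. Of these 50, 31 were at least 2-fold higher, 25 at least 4-fold higher and 5 at least 2-fold lower in dek35 as deposited, and 25, 23 and 8 relative to the median ratio. However, 18 of the 50 spanned under 200 bp and 10 were listed at 0 in wild type; without those 10 the numbers were 21, 15 and 5 as deposited, and 15, 13 and 8 relative to the median ratio. Together all 50 held 15.3% of summed FPKM in wild type. Loci picked for a high value in 1 library tend to be lower in the other. The most abundant wild-type locus, a 723-bp locus on chromosome 7, had 90938 FPKM in wild type and 1476 in dek35, 61.6-fold lower (111-fold with median-of-ratios size factors). The most abundant dek35 locus, a 305-bp locus on chromosome 10, had 24374 FPKM in dek35 and 1789 in wild type, 13.6-fold higher (7.59-fold with median-of-ratios size factors). FPKM divides by length, so these shares weigh short loci more than a share of reads would.

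**Figure D1:**
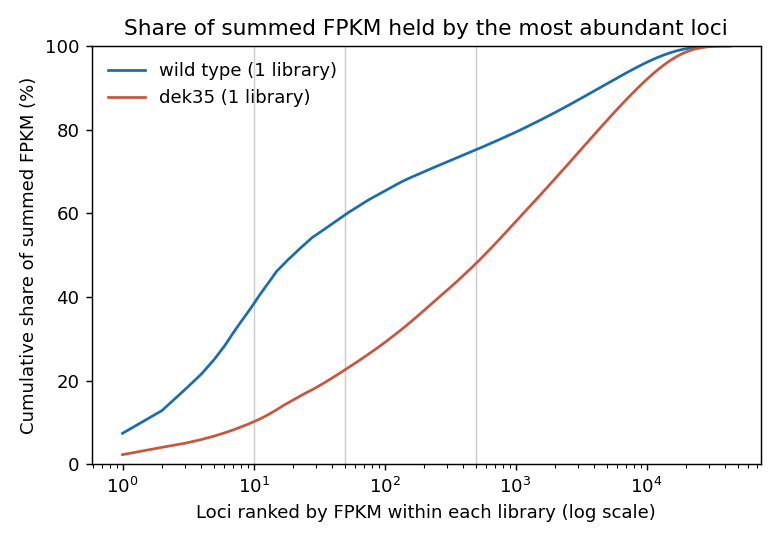
Cumulative share of summed FPKM (%) against the rank of a locus within its own library (log scale), 1 line per library; grey lines mark the ranks 10, 50 and 500. The wild-type line stands at 38.3% at rank 10 and 59.6% at rank 50, and the dek35 line at 10.1% and 22.6%.

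Part of the lower abundant loci were neighbours in the genome. Among 175 abundant loci (mean of at least 500 FPKM over both libraries, span of at least 200 bp), 7 groups of neighbours were found (5 when only 1 row was kept for each pair of coordinates), and in 3 of these every abundant locus was more than 4-fold lower in dek35. Together the 22 abundant loci of these 3 groups held 35.4% of summed FPKM in wild type and 0.402% in dek35, a 102-fold difference in summed FPKM (175-fold relative to the median ratio of all loci compared). Relative to the median locus, 40 of the 175 abundant loci were at least 4-fold lower, and 18 of these lay outside the 3 groups. The groups were defined after the values were seen.

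On chromosome 4, from 5094105 to 5561370 in the coordinates of the files, 15 abundant loci summed to 152969 FPKM in wild type and 1132 in dek35, a 135-fold difference. Their log2 ratios ran from -8.85 to -5.74. The 3 groups were singled out because every abundant locus in them was lower, so a low place among random sets largely follows from that choice. None of 10000 random sets of 15 abundant loci had a lower median than these 15 rows. Of these 15 rows, 11 share their coordinates with another row, so that the 15 lie at 10 pairs of coordinates, and how the quantification divided reads among such rows is not given in the sources used here. Another 16 loci of lower level were entered in the same interval: 5 were at least 4-fold lower relative to the median locus, 8 were within 2-fold of it and 3 were at least 2-fold higher. Of the 5 lower ones, 4 have the coordinates of an abundant locus. On chromosome 7, from 18755936 to 18878182, 4 abundant loci summed to 234144 FPKM in wild type and 2622 in dek35, an 89.3-fold difference with log2 ratios from -8.50 to -5.68 (percentile 0.46 of random sets of abundant loci). The 2 other loci entered in that interval were also at least 4-fold lower. On chromosome 4, from 29951761 to 30091004, 3 abundant loci summed to 47812 FPKM in wild type and 510 in dek35, a 93.8-fold difference (percentile 2.85, above the limit of 2.5 that was set for standing outside random sets, and 2.05 with 1 row for each pair of coordinates, an alternative added after the data were seen). These 3 lie at separate coordinates. Both further loci entered there were at least 4-fold lower, but each has the coordinates of 1 of the abundant loci. With median-of-ratios size factors the differences of these 3 groups, in the same order, were 242-fold, 160.3-fold and 168-fold.

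**Figure D2:**
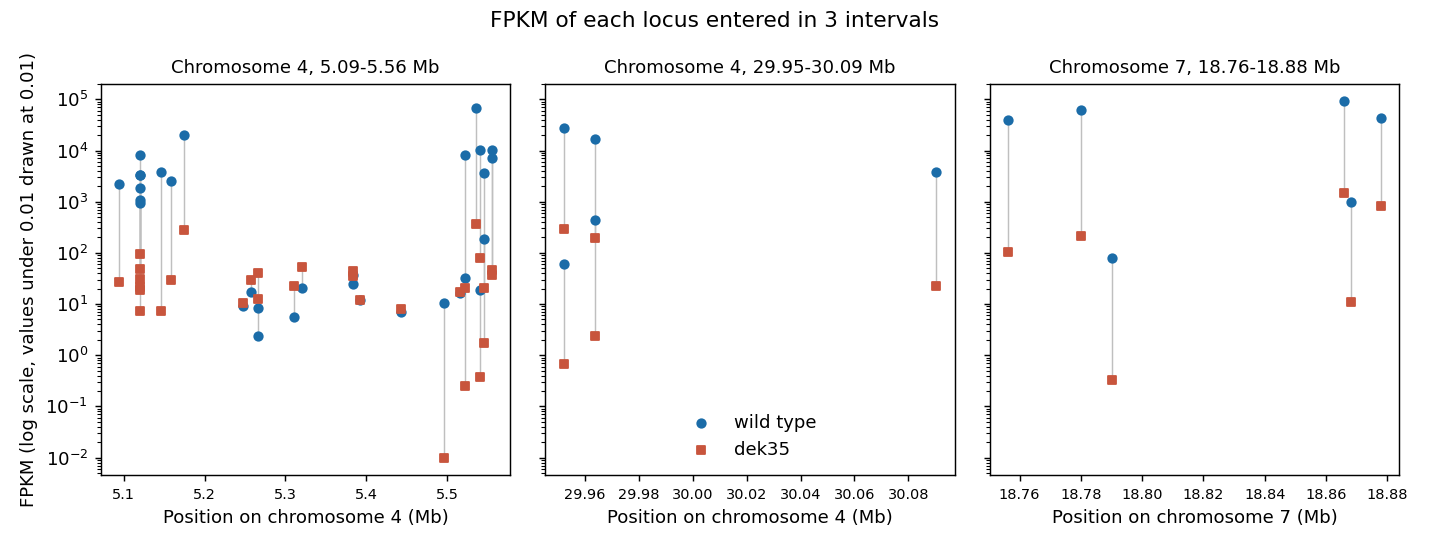
FPKM (log scale) of every locus entered in 3 intervals on chromosomes 4 and 7, against position in Mb; circles are wild type, squares dek35, 1 library each, and grey lines join the values of a locus. The abundant wild-type loci at both ends of the first interval lie far above their dek35 values, whereas most low loci in its middle lie close together; in the other 2 intervals every locus is lower in dek35.

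The other 4 groups of abundant neighbours differed less in summed FPKM. In the order given here, their median ratios stood at percentiles 11.81, 17.56, 79.21 and 50.64 of random sets of abundant loci. A chromosome 7 group, from 120206897 to 120236057, held 3 loci with log2 ratios from -7.26 to -1.18. They summed to 46259 FPKM in wild type and 9356 in dek35, a 4.94-fold difference (8.87-fold with median-of-ratios size factors). Relative to the median locus its highest log2 ratio was -1.96, so on that scale this group only just missed the 4-fold limit. The 3 rows lie at only 2 pairs of coordinates. On chromosome 6, from 38116490 to 40052652, 4 loci summed to 5631 FPKM in wild type and 2509 in dek35, 2.24-fold lower (4.03-fold with median-of-ratios size factors). Their log2 ratios ran from -8.84 to 0.68, the last lying just under the median locus (a difference of -0.099). On chromosome 6, from 136703065 to 137603656, 4 loci summed to 2180 FPKM in wild type and 5174 in dek35, 2.37-fold higher (1.32-fold with median-of-ratios size factors), with log2 ratios from 0.995 to 2.27. On chromosome 1, from 196795505 to 197304338, 3 loci summed to 4663 FPKM in wild type and 6405 in dek35, 1.37-fold higher as deposited but 0.765 times the wild-type sum with median-of-ratios size factors; these rows, too, lie at 2 pairs of coordinates. In both chromosome 6 groups the 4 rows lie at 3 pairs of coordinates. The last 2 groups had median ratios 0.36 above and 0.20 below that of all loci (log2), so they stood close to the general shift described next.

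The second question was how many loci differed between the genotypes and in which direction. Across 17514 loci entered, 80.2% had a ratio above 0, and the median log2 ratio of dek35 to wild type was 0.78, or 1.71-fold (95% interval of the median across loci 0.76 to 0.80; loci are not independent replicates). On the deposited scale, 7065 loci were at least 2-fold higher in dek35 and 908 at least 2-fold lower, so that 88.6% of these were higher. At 4-fold, 2061 were higher and 366 lower; 157 loci entered were listed at 0 in dek35, and without loci listed at 0 in either library 209 were at least 4-fold lower. Relative to the median locus, 2797 loci were at least 2-fold higher and 2519 at least 2-fold lower, so that 52.6% were higher. Without a minimum level this share was 71.7%, but the added low loci also lowered the median itself, to 0.31. With the minimum, 12198 loci (69.6%) lay within 2-fold of the median locus. At 4-fold relative to the median, 787 were higher and 715 lower. The size of the excess of higher loci depended on the scaling between the libraries. Scaling to the totals without the 50 most abundant loci, here those with the highest mean FPKM of both libraries, left a median of 0.12. It gave 3243 loci at least 2-fold higher and 2057 lower (61.2% higher).

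**Figure D3:**
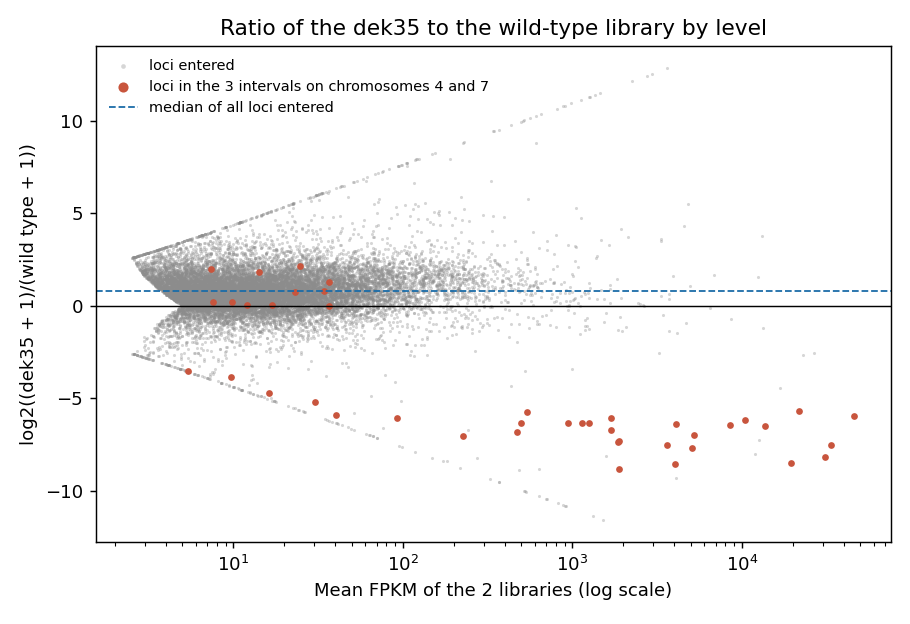
Log2 ratio of dek35 to wild type (pseudocount of 1) against the mean FPKM of the 2 libraries (log scale) for 17514 loci; red points are all loci entered in the 3 intervals on chromosomes 4 and 7. The dashed line is the median log2 ratio of 0.78, and the straight edges of the cloud are loci listed at 0 in 1 library.

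The differences depended on the level of the locus. Among 224 loci with a mean of at least 500 FPKM, 24.1% were at least 4-fold lower and 17.9% at least 4-fold higher relative to the median locus. These include loci under 200 bp. Of the 175 that span at least 200 bp, 40 were at least 4-fold lower and 23 at least 4-fold higher. Among 994 loci between 100 and 500 FPKM, the dek35 library was the higher one: their median stood 0.47 (log2) above that of all loci, 291 were at least 2-fold higher and 112 at least 2-fold lower. Loci between 30 and 100 FPKM had a median 0.09 above that of all loci, with 583 of 3156 at least 2-fold higher and 393 lower. The 6363 loci between 10 and 30 FPKM had a median 0.11 below that of all loci (a difference of -0.11), with 791 at least 2-fold higher and 924 lower. The median log2 ratios of the 10 chromosomes ran from 0.73 on chromosome 10 to 0.83 on chromosome 5.

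The largest ratios belonged to very short loci listed at 0 in 1 library, for which no fold is given. The 2 highest in dek35 were chromosome 1, 33962876 to 33962958, with 7275 FPKM, and chromosome 1, 160710769 to 160710852, with 5866 FPKM, both listed at 0 in wild type. The 2 lowest were chromosome 7, 55502306 to 55502400, with 3051 FPKM in wild type, and chromosome 1, 85075846 to 85075947, with 2640 FPKM, both listed at 0 in dek35. Of the 20 highest ratios 17 belonged to loci under 200 bp, and of the 20 lowest 15 did.

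Loci of the mitochondrial genome, on whose transcripts the DEK35 protein acts, had values near or at 0 in both libraries. Genes that every cell uses were listed at 0 in 1 library or the other, so these values cannot be read as transcript levels. Of 37 mitochondrial loci, 15 were above 0 in both libraries, 13 in dek35 alone and 9 in wild type alone, and 30 were under 1 FPKM in both. The nad4 locus (mitochondrial genome, 76132 to 84976) had 0.219 FPKM in dek35 and was listed at 0 in wild type. The nad7 locus (237577 to 243574), also a complex I subunit, had 0.0689 FPKM in dek35 and was listed at 0 in wild type. The locus that starts with nad5 (204632 to 207081), which also covers a further open reading frame, had 0.0645 FPKM in dek35 and 0.0806 in wild type. Outside the rule for naming loci, the atp6 locus (562726 to 563958), an ATP synthase subunit, had 0.273 FPKM in dek35 and was listed at 0 in wild type. The locus that overlaps cox3 (441570 to 442510) went the other way, with 0.125 FPKM in wild type, and was listed at 0 in dek35. No difference in mitochondrial transcripts could be assessed from such values, and a value per locus does not measure splicing. Only 2 mitochondrial loci passed 5 FPKM, both in dek35: the region 548031 to 548695, which overlaps no gene in the table, had 12.8 FPKM in dek35 and 0.545 in wild type, and 1 of 3 rows at 111497 to 115826 had 6.27 and 0.629. Of the 15 loci above 0 in both libraries, 8 were higher in dek35. Summed over all mitochondrial loci, dek35 had 32.2 FPKM and wild type 7.37, and without the 2 loci over 5 FPKM the sums were 13.1 and 6.20. All 5 plastid loci were listed at 0 in dek35 and reached at most 0.0829 FPKM in wild type.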

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

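No paired analysis was possible because each genotype has 1 library; for the same reason no replicate could be left out, and depth is unknown. Of 104 values under 10 alternatives 34 moved, that is, a count, share or ratio of sums by over 1.5 times, or a median out of its 95% interval across loci. Counts relative to the median could hardly move under another scaling, since 1 factor on dek35 changes them only through the pseudocount. The share of values that moved therefore understates the dependence on scaling. The median log2 ratio kept its sign under all 10, although its interval with median-of-ratios size factors (-0.0081 to 0.024) includes 0. That scaling brings the median near 0 by design, and the alternatives without another scaling leave a shift of all loci in place. The kept sign is therefore no evidence of a direction. The log2 ratio of the summed FPKM of the abundant loci in the 3 intervals, -6.67 as deposited, can change under only 5 of the 10; it was -6.46 with equal FPKM totals, -6.48 without rows that share coordinates (9 of 22 loci left) and as low as -7.52 with median-of-ratios size factors. Scaling moved the median log2 ratio of 0.78 to 0.98 (equal FPKM totals), 0.0083 (median-of-ratios), 0.10 (upper quartile) and 0.12 (totals without the 50 most abundant loci). In that order, the last 3 gave 2790, 3155 and 3243 loci at least 2-fold higher, 2437, 2131 and 2057 at least 2-fold lower, 784, 890 and 901 at least 4-fold higher, and 652, 589 and 577 at least 4-fold lower; these scalings multiply every dek35 value by 1 factor, which is the cause of the change. Without a minimum level the median was 0.31, and 1519 loci were at least 2-fold lower. Relative to that median, 6386 were at least 2-fold higher and 2520 lower (71.7% higher), and at 4-fold these were 1410 and 607. The added low loci, whose ratios the pseudocount pulls toward 0, lowered the median, so loci of higher level stood further above it. On the deposited scale, 86.4% of loci past 2-fold were higher without a minimum, against 88.6% with it. With a minimum of 20 FPKM, which leaves 7948 loci, the median was 0.94, 3758 and 442 loci were at least 2-fold higher and lower, and 1205 and 190 at least 4-fold; relative to the median these were 1326 and 1313, and 418 and 412. A pseudocount of 0.1 gave a median of 0.84. Leaving out loci listed at 0 in either library, an alternative added after the data were seen, left 209 loci at least 4-fold lower where 366 had been, through fewer loci. The comparison of FPKM with another deposited unit and the alternatives for gene lists were not run, since FPKM is the only unit used here and no list had 3 loci entered.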

Other observations

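The tests in this part were chosen after the values they bear on had been seen, except the scaling to the totals without the 50 most abundant loci, which was planned, and none compares replicates.

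Abundant loci outside the 3 strongly lower intervals on chromosomes 4 and 7 went both ways. Of 153 such loci, 18 were also at least 4-fold lower in dek35 relative to the median locus, so the decrease was not confined to the intervals. Among all 175 abundant loci, 37 were at least 2-fold higher, 62 at least 2-fold lower and 76 within 2-fold of the median locus, whereas on the deposited scale 64 were at least 2-fold higher and 47 at least 2-fold lower. In windows of 5 Mb with at least 20 loci, chromosome 4 from 5000001 to 10000000 had the highest share of loci at least 4-fold lower (25 of 58, 43.1%, against 4.09% of all loci on the 10 chromosomes). That was above the highest window in any of 1000 shuffles of positions (30%). The 25 loci include the 15 abundant and 5 other lower loci of the interval from 5094105 to 5561370. The window thus largely restates that group. Without rows that share coordinates this window was still the highest, but at 30% (9 of 30), a value that 1 of 1000 shuffles reached. With all rows, a window on chromosome 1, from 160000001 to 165000000, also stood at 30% (6 of 20), as high as the highest window of 1 of 1000 shuffles. For loci at least 4-fold higher, the highest window held 20%, and 255 of 1000 shuffles gave one as high. Neighbouring loci outside the groups of abundant loci had weakly similar ratios (Spearman's rho 0.07 across 12967 pairs of loci, which are not independent replicates; shuffled orders of all loci gave at most 0.028).

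Most loci were higher in the dek35 library. Against counting noise from low depth alone, among 4374 loci with a mean of at least 30 FPKM the median log2 ratio was 0.94 (95% interval across loci 0.90 to 0.98), where such noise would spare well-measured loci. A difference in the totals or scaling behind the FPKM would shift all loci alike, so these values cannot exclude it. Composition stays a candidate explanation, since FPKM is relative to all mapped fragments and 50 loci held 59.6% of the wild-type total. Scaling to the totals without the 50 loci of highest mean FPKM over both libraries, not picked on wild type alone, brought the median to 0.12. It would do the same to a true rise of the other loci. Composition, a scaling difference and a true rise in transcripts per cell therefore cannot be told apart. Nothing in the tables gives an absolute amount.

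The abundant loci of 3 intervals on chromosomes 4 and 7 were lower in dek35. Reads moved between near-identical copies within an interval would leave their sum about equal. Relative to the median locus the sum over 22 loci was 175-fold lower, but their groups were picked for being lower. Over all loci entered, the longer chromosome 4 interval summed to 154312 FPKM in wild type and 1427 in dek35. The shorter one summed to 48320 and 513, and the chromosome 7 interval to 235206 and 2633. The picked loci set the ends of each interval and held 152969, 47812 and 234144 FPKM of these wild-type sums, in the same order. The sums are therefore no separate check on that choice. They show only that the other loci entered inside the intervals did not take up the difference. Copies outside the intervals were not examined. A single missing segment spanning the longer chromosome 4 interval in the dek35 material would lower the other loci inside it as well, and 11 of 16 were not 2-fold lower, or 11 of the 12 that do not have the coordinates of an abundant locus; separate losses at its ends stay open. For the 2 smaller intervals a missing segment cannot be told apart from lower transcription, because only 4 other loci were entered there, all at least 4-fold lower, and 2 of these have the coordinates of an abundant locus. Their abundant loci still summed to 2622 FPKM (chromosome 7) and 510 FPKM (chromosome 4) in dek35. The lowest dek35 value of the 22 loci was 7.18 FPKM. If a segment were missing from all of the material, these reads would have to come from elsewhere, such as copies at other places. Their source was not tested, so these values do not exclude a missing segment. An effect of the dek35 genotype on endosperm filling or its timing, and sequence differences between the alleles and the reference that hinder mapping, stay open and were not tested.

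Of 282 loci under 200 bp, 67.0% were listed at 0 in 1 library, 115 of them in wild type and 74 in dek35. Loci of at least 1000 bp with the same higher FPKM were listed at 0 in 0.803% of cases. Being listed at 0 thus went with short span rather than with low FPKM. FPKM divides by length, so at the same FPKM a shorter locus generally holds fewer fragments. Short span and a low number of fragments therefore cannot be told apart here. How the quantification treats very short loci is not given in the sources used here, so the reason was not settled. No biological explanation was tested for these loci.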
